A study of Homo sapiens with 6 samples.

How the data were processed

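RIP-seq libraries of MDA-MB-231 and MCF-7 cells expressing FLAG-tagged MDM2 were described in 6 samples, 1 library per group: anti-FLAG precipitate, normal mouse IgG precipitate and input in each line. Per the labels' protocols, RNA was recovered with antibody on protein A/G beads, and libraries were made from RNA depleted of ribosomal RNA. Peak lists of the 4 precipitates were analysed, 1 list per library with no pooling, and the input libraries are not analysed here. The labels' treatment field gives the anti-FLAG precipitation for the input samples too, and the sample titles were followed.

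Reads were aligned with Bowtie2 2.2.8 per the submitters' processing notes. The peak caller, genome build, annotation and filters are not given in the sources used here. Per the file headers, each peak has a log2 fold, and the authors' comparison library for it is not stated. The deposited score of a peak rises with its significance and is infinite for 20, 0, 4 and 20 peaks of the MDA-MB-231 FLAG, MDA-MB-231 IgG, MCF-7 FLAG and MCF-7 IgG lists. The deposited p-value and adjusted p-value come from a caller whose test is not stated, and the −log10 columns are those deposited values on a log scale. Other deposited columns give the length of a peak's span, introns included, and its number of blocks, which come in steps of 25 bp. Folds were used to describe and rank peaks within a list. The least strict adjusted p-value in a list was 1.82e-05, 0.000134, 6.77e-06 and 5.91e-06 in the same order, so the lists hold only peaks past a strict threshold and a missing peak is not a missing RNA. No read counts were at hand, so depth is unknown, and a longer list can come from a deeper library.

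Overlap was computed from blocks on the same strand with a minimum of 1 bp. A FLAG-specific peak shares no base with an IgG peak of the same line, and a FLAG-specific gene has a FLAG peak and no IgG peak there. Shares have exact Clopper-Pearson intervals at 95%. Without read counts no test between conditions was run, and no p-value was computed. Lists were set against 10000 random lists of the same size, matched on biotype and on 10 groups of gene length, and as an alternative drawn from named genes with a peak in any library. Percentiles give the percent of random lists with fewer FLAG-specific genes and describe these libraries only.

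The lists give Ensembl gene IDs without names, and the RefSeq table at hand (assembly GRCh38.p14) holds no Ensembl IDs, exons or strands. The build was therefore settled from the peaks: 203 of 13520 peaks had an edge exactly on a gene edge at the positions as given, against at most 8 at 9 other shifts. An ID was named when a single RefSeq gene shared bases with every block of all its peaks and no other ID led to that gene. This named 2851 of 3605 IDs (79.1%). Of the rest, 251 fitted several genes, 97 fitted no single gene and 406 led to a gene also given by another ID or had no peak of their own. The reference's coordinates are not printed.

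Several steps differ from the written design because exons were lacking. The makeup of peaks by exon, intron and UTR was not computed, random lists were matched on the length of the gene span in place of exonic length, and gene assignment by exon overlap was not run. The rule for named genes was fixed before the data were examined: per line the 12 FLAG-specific genes and 10 FLAG-specific lncRNA genes with the highest fold, from peaks on 1 gene, then the 15 lncRNA and 15 other genes of both lines with the smallest rank sum, always MDM2 and TP53, and up to 4 members of each list per line. The lncRNA parts named none, and the rule reached only IDs that could be named.

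The 12 gene lists fixed before the data were examined were lncRNAs studied in cancer, p53 targets, mRNAs reported to bind MDM2, small structural RNAs, mitochondrial transcripts, ribosomal proteins, histones, luminal genes, mesenchymal genes, ubiquitin and MDM2 partner genes, splicing genes and immune markers. A further 3 lists of 20 markers each, of basal epithelium, hepatocytes and stroma, were written after the leading genes had been seen and before their own members were looked up. Alternatives covered the overlap rule, the fold minimum (5-fold), gene assignment, the IgG exclusion and the background of the lists.

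The steps were tested on simulated data. Covered bases equalled a direct count for 200 of 200 peaks. Of 1000 planted genes 94.1% were named and 0 wrongly. A wrong name was not possible there, as each planted gene was always among its own candidates. The planted genes were protein-coding with a block near each end, so the share named does not carry over to the real peaks. For FLAG-specific genes in MDA-MB-231, 68.5% of 200 simulated lists enriched 4 times reached the 95th percentile against 2% without enrichment, and for those in MCF-7 60.5% against 4.5%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used.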

Results

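RNA immunoprecipitation followed by sequencing (RIP-seq) was carried out in the breast cancer lines MDA-MB-231 and MCF-7, which per the labels carry mutant and wild-type p53. Both lines had been transfected to express FLAG-tagged MDM2, the ubiquitin ligase that holds p53 in check. In each line 1 library came from an anti-FLAG precipitate, 1 from a normal mouse IgG precipitate and 1 from input RNA. Peak lists of the 4 precipitates were used, and the 2 input libraries are not analysed here. The FLAG list held 3702 peaks on 1671 gene IDs in MDA-MB-231 and 4618 peaks on 1850 gene IDs in MCF-7. The IgG lists held 1135 peaks on 897 gene IDs and 4065 peaks on 1134 gene IDs. Read depth is unknown, and with 1 library per group no difference between conditions has a replicate check. Intervals below are exact Clopper-Pearson intervals at 95% and cover counting error only. All fold values and adjusted p-values of peaks are the authors', and the library that the folds are relative to is not stated.

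The first comparison asked which RNAs were recovered with anti-FLAG and not with IgG in p53-mutant MDA-MB-231 cells. Among the highest folds were genes of stratified and basal epithelium, a grouping made after the leading genes had been seen. COL17A1, a hemidesmosome collagen, had 9 FLAG peaks and a top log2 fold of 13.25. DSG3, a desmosomal cadherin, reached 12.37, IRF6, a transcription factor of keratinocyte differentiation, 12.37, and SERPINB5, the serpin maspin, 12.08. None of these 4 genes had an IgG peak in either line. Of the 3702 FLAG peaks, 3436 (92.8%, interval 91.9 to 93.6) shared no base with an IgG peak, and 1367 of 1671 genes (81.8%, interval 79.9 to 83.6) had no IgG peak. These genes are called FLAG-specific. The IgG list had 593 genes of its own.

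The 12 named FLAG-specific genes of MDA-MB-231 also included SFRP1, a secreted Wnt antagonist with 9 peaks and an adjusted p of 3.77e-09 at its top peak, and the keratins KRT15 and KRT16 with top log2 folds of 11.84 and 11.70. The histone gene H4C4 followed with 11.34, FGFBP1 with 11.33, CLCA2 with 11.31, the laminin chain gene LAMA3 with 11.22 and the cadherin family gene FAT2 with 11.20 over 30 peaks. The top COL17A1 peak spanned chromosome 10 from 104039517 to 104057015 in 27 blocks, with an adjusted p of 1.03e-10. The top DSG3 peak was a single block on chromosome 18 from 31475724 to 31476598, and that of IRF6 a single block on chromosome 1 from 209785667 to 209786416. Coordinates are those of the files, counted from 1, and the build is GRCh38 as inferred from the positions. The annotation at hand had no exons, so exon, intron and UTR positions are not given. Keratin and histone genes have near-identical copies, so the assignment of their peaks to 1 copy is uncertain. Without the genes that reached a log2 fold of 8 in any library, 1310 FLAG-specific genes were left.

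**Figure D1:**
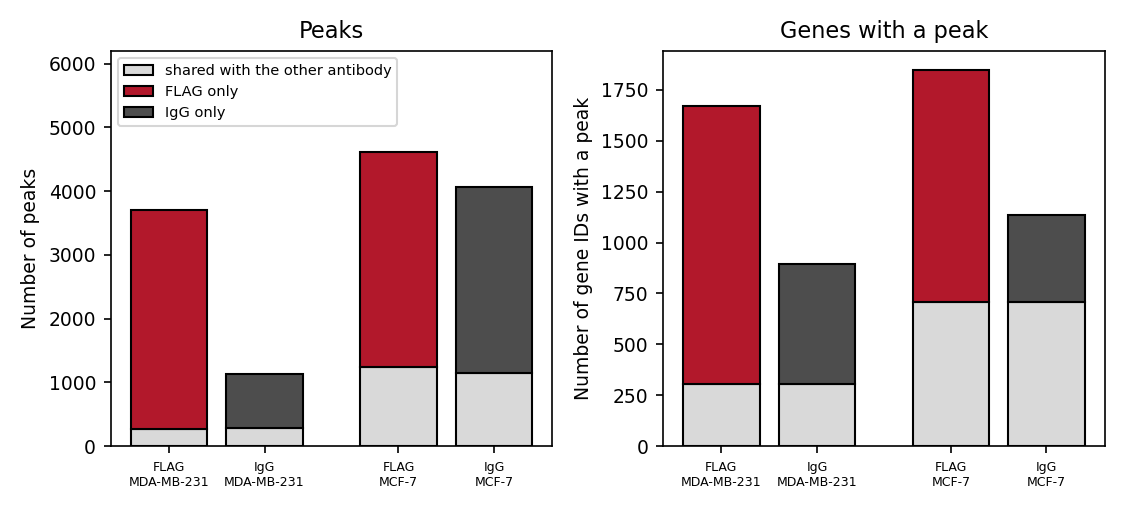
Number of peaks (left) and of gene IDs with a peak (right) in the FLAG and IgG lists of both lines, 1 library per bar, split into those shared with the other antibody of the same line (light grey) and those of 1 antibody alone (red, FLAG; dark grey, IgG). The FLAG-only part is 3436 of 3702 peaks in MDA-MB-231 and 3379 of 4618 peaks in MCF-7.

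The same comparison in p53 wild-type MCF-7 cells again had basal epithelial genes among the highest folds. KRT15 had a top log2 fold of 11.40, the calcium-binding protein gene S100A2 11.28 and COL17A1 10.82, with IRF6 ranked between the last pair, and none of the 4 had a peak in the MCF-7 IgG list. Fewer FLAG peaks were free of IgG overlap in this line. They numbered 3379 of 4618 (73.2%, interval 71.9 to 74.4), and 1144 of 1850 genes (61.8%, interval 59.6 to 64.1) were FLAG-specific. A further 706 genes had peaks in both lists, and 428 had IgG peaks only.

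The other named genes of MCF-7 were DSG3 (10.77), SFRP1 (10.66), FAT2 (10.54), CLCA2 (10.37), the laminin chain gene LAMC2 (10.25), the transcription factor gene TFCP2L1 (10.13), S100A8 (9.95) and KRT6A (9.85), each with its top log2 fold. The top KRT15 peak lay on chromosome 17 from 41517536 to 41518455, and the S100A2 peak on chromosome 1 from 153561108 to 153561282. Without the genes that reached a log2 fold of 8 in any library, 1102 FLAG-specific genes were left. The MCF-7 IgG list had high folds of its own, on genes with no MCF-7 FLAG peak. They included the mucin gene MUC5AC (12.09), the mesenchymal cadherin gene CDH11 (11.32), the collagen gene COL6A3 (11.02) and FN1, which encodes fibronectin (9.75). MUC5AC, CDH11 and COL6A3 were chosen after their values were seen. The MDA-MB-231 IgG list had no peak of that height, and its maximum was 3.86. The shares of the 2 lines come from IgG lists of different length, and the difference between them was not tested.

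The comparison of both lines asked which RNAs were recovered with FLAG-MDM2 whether p53 was mutant or wild type. In all, 514 genes were FLAG-specific in both, which is 37.6% of those of MDA-MB-231 and 44.9% of those of MCF-7. Independent lists of these lengths among the 3605 gene IDs with a peak in any of the 4 lists would share 434. Over the same 3605 IDs, all FLAG genes of both lines shared 800 where independent lists would share 858, so the side on which the overlap falls depends on the genes counted. The 15 named genes of both lists were COL17A1, IRF6, DSG3, KRT15, SFRP1, CLCA2, FAT2, SERPINB5, CDH1, TFCP2L1, C1orf116, KRT6A, KRT5, KRT16 and DSC3. CDH1, the epithelial cadherin E-cadherin, had a top log2 fold of 10.71 in MDA-MB-231 and 9.75 in MCF-7. KRT5, a basal keratin, had 10.08 and 9.53, and KRT16 had 11.70 and 5.14. CDH1 is also on the fixed list of luminal genes typical of MCF-7. Whether either line expresses these genes is not known here, as the input libraries were not analysed. The folds alone therefore do not show binding by FLAG-MDM2. In MDA-MB-231, 694 FLAG-specific genes had no FLAG peak in MCF-7, and 535 FLAG-specific genes of MCF-7 had none in MDA-MB-231. Of the FLAG peaks of MDA-MB-231, 34.0% shared a base with an MCF-7 FLAG peak. Without the genes of log2 fold 8 or more, 472 shared genes were left.

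**Figure D2:**
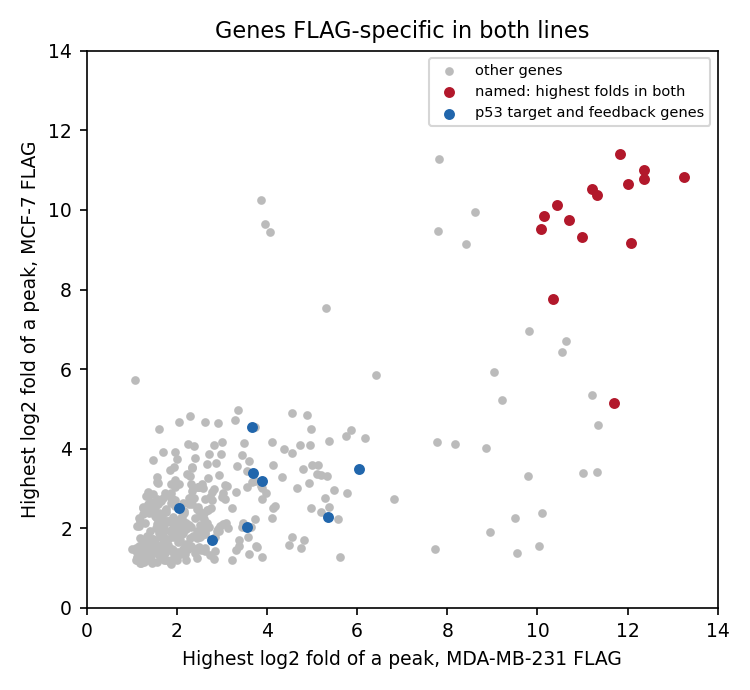
Highest log2 fold of a peak per gene in the MDA-MB-231 FLAG list (x axis) and the MCF-7 FLAG list (y axis) for the 420 named genes that were FLAG-specific in both lines, 1 library per axis. The 15 genes with the smallest rank sum (red) lie at the upper right, COL17A1 at 13.25 and 10.82, and the p53 target genes (blue) lie at lower folds.

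MDM2 itself had peaks spread along the gene in both FLAG lists. MDA-MB-231 had 17 FLAG peaks on MDM2, between 68815681 and 68845493 on the plus strand of chromosome 12, with log2 folds from 1.23 to 4.55 and no IgG peak. MCF-7 had 18, between 68816847 and 68845793, with folds from 1.23 to 4.46. MCF-7 also had 1 IgG peak on MDM2, from 68839294 to 68839468 with a log2 fold of 1.31, so MDM2 was not FLAG-specific there. Both lines carried an MDM2 plasmid, and the peak lists do not separate its RNA from that of the gene. No peak of any of the 4 lists lay on TP53.

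**Figure D3:**
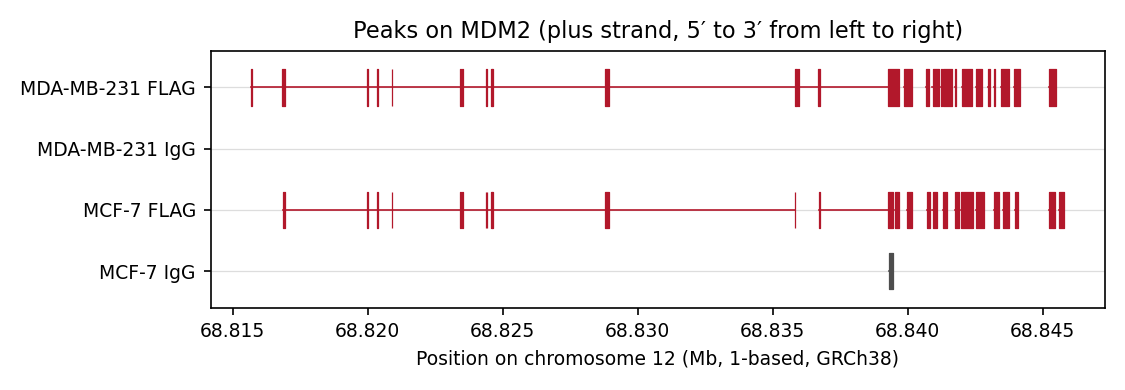
Peaks on MDM2 in the 4 lists, by position on chromosome 12 in Mb (GRCh38, inferred); filled boxes are the blocks of a peak and thin lines join the blocks. The FLAG lists hold 17 (MDA-MB-231) and 18 (MCF-7) peaks, the IgG lists 0 and 1.

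Of 30 listed p53 target and feedback genes, 12 were FLAG-specific in MDA-MB-231 and 9 in MCF-7, 8 of them in both lines. None had an IgG peak in MDA-MB-231, and MDM2 was the 1 member with an IgG peak in MCF-7. The 12 of MDA-MB-231 include MDM2, whose peaks cannot be told from RNA of the plasmid. BTG2, an antiproliferative gene, had a top log2 fold of 6.04 in MDA-MB-231 and 3.49 in MCF-7. PHLDA3 had 5.36 and 2.27, ZMAT3 3.66 and 4.53, POLH, a translesion polymerase gene, 3.90 and 3.20, and CDKN1A, which encodes the cell cycle inhibitor p21, 3.69 and 3.39. All of 10000 random lists matched on biotype and gene length held fewer FLAG-specific genes in both lines. Among random lists of genes with a peak in any library, the percentiles were 99.99 and 99.43. In the same FLAG lists basal keratins such as KRT5 stood at log2 folds of 10.08 and 9.53.

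**Figure D4:**
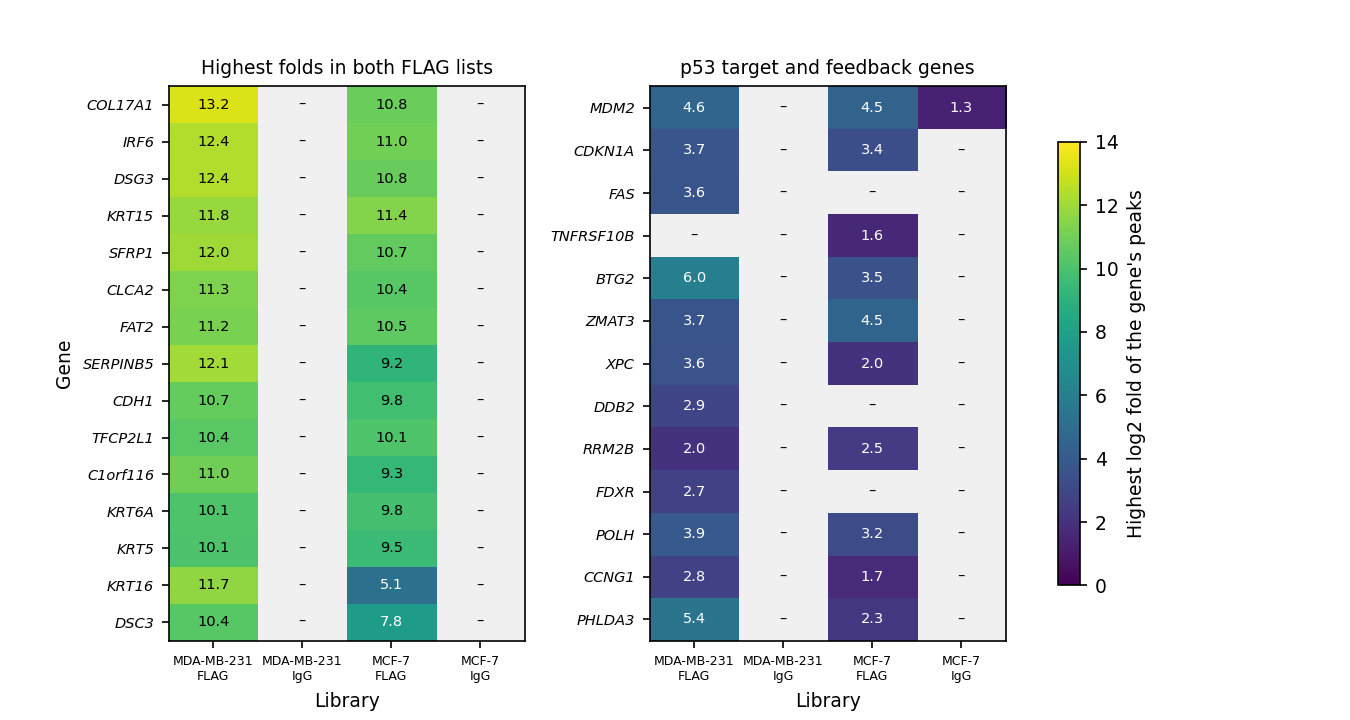
Highest log2 fold of any peak of each gene in the 4 lists (colour and printed value; a dash marks a gene with no peak), for the 15 genes named across both lines (left) and the p53 target and feedback genes with a peak (right). The left genes range up to 13.25 in MDA-MB-231 FLAG. They have no IgG value because they were chosen among genes FLAG-specific in both lines. MDM2 is the p53 list member with an IgG value, 1.31.

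Among 8 mRNAs reported to bind the MDM2 protein, 3 were FLAG-specific in MDA-MB-231 and 4 in MCF-7. MDM2 itself was among the 3 in MDA-MB-231, although its peaks cannot be told from RNA of the plasmid. The oncogene MYC had top log2 folds of 3.89 and 1.28, and CDKN1A was the other shared member. XIAP, an inhibitor of caspases, and VEGFA, an angiogenic factor, were FLAG-specific in MCF-7 with 2.73 and 1.98 and had no peak in MDA-MB-231. The percentiles were 99.45 in MDA-MB-231 and 99.98 in MCF-7 among matched random lists, and 73.4 and 96.4 among lists of genes with a peak. MDM2 and CDKN1A are members of the p53 list too, so these lists are not independent.

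Transcripts of cytosolic ribosomal proteins were FLAG-specific for 22 of 77 genes in MDA-MB-231, with RPL34 (3.60), RPS19 (2.87), RPS14 (2.09) and RPS6 (1.89) at the highest log2 folds, and for 4 in MCF-7, namely RPL27A (1.55), RPS6 (1.49), RPL34 (1.35) and RPL3 (1.21). The percentiles were 100 in MDA-MB-231 and 93.2 in MCF-7 among matched random lists, and 99.95 and 0.28 among genes with a peak, where the MCF-7 count turned from above to below the random median. Histone genes were FLAG-specific for 9 of 36 in MDA-MB-231, led by H4C4, H2BC9 (9.83), H1-5 (6.25) and H3C8 (5.39), and for 1, H4C4 (4.61), in MCF-7. Histone genes with an IgG peak numbered 8 in MDA-MB-231 and 4 in MCF-7, and histones took 0.539% of the FLAG genes and 0.892% of the IgG genes in MDA-MB-231 and 0.0541% and 0.353% in MCF-7. The histone percentiles were 100 and 78.0 among matched lists and 76.0 and 0.05 among genes with a peak, again turning in MCF-7. Neither difference between the lines was tested, and copies of both families are hard to tell apart by short reads.

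Of 29 genes of ubiquitin ligases, the proteasome and MDM2 partners, 3 were FLAG-specific in MDA-MB-231 and 7 in MCF-7. FOXO3, a forkhead transcription factor, had top log2 folds of 3.30 and 4.73, YY1 2.32 and 2.04, and the nucleophosmin gene NPM1 1.12 and 1.22, and the retinoblastoma gene RB1 had 3.16 in MCF-7. The percentiles were 75.8 and 99.96 among matched lists and 8.65 and 91.6 among genes with a peak, turning in MDA-MB-231. Splicing and RNA-binding protein genes were FLAG-specific for 5 and 3 of 29, with SRSF5 at 2.22 in MDA-MB-231 and 3.36 in MCF-7 and percentiles of 98.3 and 87.7 among matched lists and 36.3 and 12.96 among genes with a peak, turning in MCF-7. No immune cell marker of 12 and no small structural RNA of 38 had a peak on a named gene.

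Of 25 luminal genes typical of MCF-7, 1 was FLAG-specific in MDA-MB-231 (CDH1) and 2 in MCF-7 (CDH1 and the zinc transporter gene SLC39A6, 1.40), at percentiles of 26.1 and 68.8 among matched random lists and 5.60 and 38.3 among genes with a peak. Of 25 mesenchymal genes typical of MDA-MB-231, 4 were FLAG-specific in that line, CAV2 (3.11), TGFBI (3 peaks), MMP14 (1.97) and EGFR (1.13), the values in brackets being log2 folds unless peaks are named, and 1, CAV2 (3.07), in MCF-7. Their percentiles were 96.1 and 33.2 among matched lists and 13.6 and 0.33 among genes with a peak, turning in MDA-MB-231. In MCF-7, 7 of the 25 had a FLAG peak, with TGFBI at 7.54, MMP14 at 6.02, CAV1 at 3.65 and CAV2 at 3.07, and 13 had an IgG peak, with FN1 at 9.75, TGFBI at 4.47, SPARC at 4.40 and MMP14 at 4.19. Mitochondrial transcripts were FLAG-specific for 3 of 15 in MDA-MB-231, ND5 (1.44), ND3 (1.22) and ND6 (1.09), and for 0 in MCF-7. The mitochondrial percentiles were 99.51 and 0 among matched lists and 85.51 and 0 among genes with a peak, below the 95th in MDA-MB-231 on the latter. A count of 0 gives a percentile of 0 by definition. The random median of the matched lists was also 0 in MCF-7, so that percentile does not show depletion.

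The design text asks for long noncoding RNAs. None of the 2851 gene IDs that could be named by position was a lncRNA gene of the reference, where 18330 genes have that class, and 2850 were protein-coding. Accordingly no lncRNA gene was FLAG-specific in MDA-MB-231, in MCF-7 or in both. TUG1, studied as a lncRNA and protein-coding in the reference used, was FLAG-specific in MCF-7 with 1 peak and a log2 fold of 1.29. It was the 1 member with a peak on a named gene among 43 listed lncRNAs. Peaks on named protein-coding genes made up 87.3% of the FLAG list (interval 86.1 to 88.3) and 85.2% of the IgG list (interval 83.0 to 87.2) in MDA-MB-231. In MCF-7 they made up 91.3% (interval 90.5 to 92.1) and 91.7% (interval 90.8 to 92.5). Nearly all other peaks lay on unnamed IDs, 471 and 168 in the FLAG and IgG lists of MDA-MB-231 and 401 and 339 in MCF-7. These shares therefore follow how often an ID could be named and do not measure noncoding peaks. In all, 754 IDs could not be named, so lncRNAs among them are not ruled out. Counting by RefSeq gene spans, with only peaks on 1 gene kept, gave 2 FLAG-specific lncRNA genes in MCF-7, ATP1A1-AS1 and SNHG16, and 0 in MDA-MB-231. The reference has no strands, so a peak on the strand opposite to such a gene would be counted too. These 2 genes are therefore uncertain.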

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

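The tests of chance high folds, of swapped IgG libraries and of p53 status were chosen after the results they measure had been seen.

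Mitochondrial transcripts took a larger share of the FLAG genes than of the IgG genes in MDA-MB-231, by 0.128 percentage points, and a smaller one in MCF-7, at -0.191 points. The lines moved in opposite directions with 1 library each, and the difference was not tested. The counts behind it are 4 and 1 genes in MDA-MB-231 and 3 and 4 in MCF-7.

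Some genes of basal epithelium were among the highest folds in both FLAG lists, a grouping made after the leading genes had been seen. The lines shared 17 gene IDs with a log2 fold of 8 or more, 52.2 times the overlap of independent lists (16 and 48.6 times with IDs of identical peaks counted once). Whether near-empty comparison libraries gave these folds cannot be told from this. The same genes may be near empty in the comparison library of each line, or in a common one, as the comparison library is not stated. RNA from another cell type in both FLAG libraries is a candidate source: 6 of 20 basal markers chosen without looking them up (KRT5, KRT14, KRT6A, DSC3, CDH3 and CSTA) had log2 folds of 3 or more in both lines, and 15 and 10 of the 20 were FLAG-specific, though 3 of the 6 (KRT5, KRT6A and DSC3) are also among the 15 named genes of both lines. Binding of these transcripts by FLAG-MDM2 is another candidate, though the same 6 markers met the bound written beforehand against binding. That bound was set aside only after the value was seen. It assumed that these lines do not express the markers, which only the input libraries, not analysed here, would show. Keratins share sequence, so the 6 are not fully separate, and without expression values binding stays open beside RNA of another cell type.

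Mesenchymal genes had IgG peaks in MCF-7, 13 of 25, and 7 of the 25 had FLAG peaks there. In the MCF-7 FLAG list 4 of the 7 reached a log2 fold of 3 or more, up to 7.54, and their source was not tested. The explanations below concern the peaks of the MCF-7 IgG library. Hepatocyte RNA may be part of the IgG library, with 5 of 20 held-out markers at a log2 fold of 3 or more (APOH, FGB, SERPINA1, TTR and AMBP), and ALB, seen beforehand, stood at 5.29, yet 12 of the 20, the abundant APOA1 and APOB among them, had no IgG peak on a named gene, and how many of the mesenchymal genes such RNA would bring was not tested. RNA of stromal cells stays open: 0 of 20 held-out stromal markers reached that fold there, which met the bound written beforehand against it. That bound could not decide, since only 3 of the 20 had a peak on a named gene in any list. The marker list also left out CDH11, COL6A3, FN1 and SPARC. Of the 3, COL6A1 (1.63) and FBN1 (1.20) had MCF-7 IgG peaks. FBN1 also had an MCF-7 FLAG peak (1.39), and TAGLN had FLAG peaks only (4.55 in MDA-MB-231 and 4.90 in MCF-7). A swap of both IgG libraries stays open too: 0 luminal genes had an MDA-MB-231 IgG fold of that size, where only 2 gene IDs of that list had one, while luminal genes had 4 IgG peak genes in MDA-MB-231 against 2 in MCF-7 and mesenchymal genes 5 against 13; against a swap, MCF-7 IgG shared 706 genes with MCF-7 FLAG (582 if independent) and 207 with MDA-MB-231 FLAG (526), and MDA-MB-231 IgG shared 304 with its own FLAG list (416) and 198 with that of MCF-7 (460), but lists of 1 line made against a common comparison library, which is not stated here, would share genes too. No biological explanation was tested.

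Targets of p53 were in the FLAG lists of both lines. A percentile of 100 among matched lists met the bound written beforehand against gene length, and argues against the length of the gene span alone. Those lists were drawn from all reference genes, with or without a peak, and were not matched on transcript length, so they cannot exclude transcript length. Histone genes also reached 100 there in MDA-MB-231, but 76.0 among genes with a peak. A tendency of well-sampled transcripts to be called in any library stays open. The percentile of 99.43 among lists of genes with a peak met the bound written beforehand against it. Those lists were not matched on abundance or on number of peaks, so they cannot decide this. A dependence on p53 status stays open. With any FLAG peak counted, 10 genes in MCF-7 over 12 in MDA-MB-231 gave a ratio of 0.833. Its exact interval was 0.323 to 2.10 for counting error only, from 1 library per line of unknown depth. The interval takes the counts as independent, although 9 of the genes had a FLAG peak in both lines. Whether MDM2 binds them or another cell type brings them stays open as well, as the 6 basal markers lie in the same libraries.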

How the results depend on the processing

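Alternatives by RefSeq spans, by strand, by names from the only protein-coding gene that fits and without genes of log2 fold 8 or more were chosen after seeing the data. Of 89 alternatives, 68 left a count within 1.5 times its value, a share within its interval or a list on its side of the 95th percentile and of the random median, 10 moved the value further, 6 took a list below that percentile and 5 turned a list from above to below the median. Of the 68, 12 could not have moved: the lncRNA counts, as no named ID is a lncRNA, and the shared count without genes of either IgG list. Within that tolerance, exclusion by peak raised the FLAG-specific genes of MCF-7 to 1659 and the shared genes to 732. With fewer peaks the counts fell: the upper part of the FLAG peaks by fold left 1804 FLAG-specific peaks in MDA-MB-231 and 1787 in MCF-7. At 5-fold or more in both lists, 1137 of 1138 FLAG peaks in MDA-MB-231 and 955 of 1100 in MCF-7 were FLAG-specific. There were 499 and 504 FLAG-specific genes, and 182 shared genes. The IgG lists kept 14 and 1195 peaks at that fold, so few IgG peaks were left to overlap in MDA-MB-231. RefSeq spans, used without strand and with only peaks on 1 gene kept, gave 2 lncRNA genes in MCF-7 in place of 0. By covered bases, named protein-coding genes took 88.9% of MDA-MB-231 FLAG and 93.7% of MCF-7 IgG, nearly all the rest being unnamed IDs. The cause of the change was not tested. The list changes came with the background of genes with a peak. The 5 that turned were, in MCF-7, ribosomal proteins (0.28), histones (0.05) and splicing genes (12.96), and in MDA-MB-231 mesenchymal (13.55) and ubiquitin genes (8.65). Targets of p53 were above the 95th in both lines. Gene assignment by exon overlap was not run, and no replicate could be left out with 1 library per group. Unknown depth limits every comparison of list lengths.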

Other observations

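The single genes named in this part were chosen after their values were seen. By number of peaks, the MDA-MB-231 FLAG list was led by FAT2 with 30 peaks, PTPN14 with 23, SYNE2 and TFCP2L1 with 21 each, and NOTCH1 had 16 with a top log2 fold of 4.99. The MDA-MB-231 IgG list held milder folds, with FAM114A1 (2.76), PSAT1 (2.61) and BIRC5 (2.48) among the highest, and PRKCA had 10 peaks with a top log2 fold of 1.69.

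The lists of the 2 antibodies were more alike within MCF-7 than within MDA-MB-231. FLAG and IgG shared 706 genes in MCF-7, 31.0% of their union, where independent lists among the 3605 IDs would share 582, and 304 in MDA-MB-231, 13.4%, where they would share 416. Both IgG lists shared 118 genes, 6.17% of their union, where independent lists would share 282. These independent counts are over IDs with a peak in at least 1 list, which lowers overlaps, so they are not a chance level. The high-fold genes of the MCF-7 IgG list, 12 at a log2 fold of 8 or more, had no gene in common with the 23 of the MCF-7 FLAG list. Held-out basal, hepatocyte and stromal markers were FLAG-specific for 15, 2 and 1 in MDA-MB-231 and 10, 1 and 1 in MCF-7.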
